A study of Glycine max
Phytophthora sojae with 128 samples.

How the data were processed

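Gene expression was measured on 128 Affymetrix arrays in seedlings of 8 soybean cultivars, ATHOW, CONRAD, GENERAL, OX20-8, PI291327, SLOAN, V710370 and WILLIAMS, which the series describes as varying in quantitative resistance to the oomycete *Phytophthora sojae*. Per the labels, roots were inoculated with *P. sojae* or mock-inoculated with water and agar, and total RNA from hypocotyl and root tissue was taken 72 or 120 h later. Each cultivar, treatment and time had 4 replicates with the letters V, W, Y and Z, which makes 32 groups of 4 arrays. The RNA of mock plants held between 2% and 16% of added RNA from *P. sojae* mycelium grown in a liquid sucrose medium, so the mock arrays serve both as uninfected soybean and as cultured *P. sojae*. The amount added to each array is not given in the sources used here. The replicate letters were treated as independent replicates, since the labels call them experimental replicates; whether each came from its own planting is not stated in the sources used here.

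The table used holds 61170 probe sets and 128 arrays with 0 missing values. Its values were deposited as log2 signal, and the submitters' processing notes name RMA (background correction, quantile normalization over whole arrays and probe set summary) without a version. The mean value of an array was 4.84 ± 0.01 (SD, n = 128). The array carries 37593 soybean, 15820 *P. sojae* and 7530 nematode probe sets. No nematode RNA was part of the design, so nematode probe sets served as the background. A probe set was tested if, in all 4 arrays of at least 1 group, it lay above the 95th percentile of the nematode probe sets of the same array, which was 4.18 ± 0.09 (SD, n = 128). In the text "above background" means above this percentile of the same array. A difference written "at least", used for soybean probe sets only, has a group with no array above background, and its values below the percentile were set to it. This left 27289 soybean (72.6%) and 5290 *P. sojae* (33.4%) probe sets, against 5.51% of the nematode probe sets. The nematode percentage follows largely from the rule, whose cutoff comes from the same probe sets, and is not a measured rate of false detection. Ribosomal RNA probe sets and manufacturer's controls were left out.

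Of the soybean probe sets, 8677 have 1 gene in the annotation, 370 have several and 28546 have none. The probe sets with 1 gene that were tested number 7220, for 5215 genes. Only probe sets with exactly 1 gene are named by gene, other soybean and nematode ones by their identifier with _ in place of its dots, and of the tested ones 1350 have a symbol other than a LOC number. No *P. sojae* probe set has a gene name in the tables used. Gene symbols were matched to a gene list of *Glycine max* for 8652 of the 8677 Entrez identifiers.

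Soybean probe sets were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 32 groups, empirical Bayes variances and Benjamini-Hochberg adjustment over the tested probe sets. A probe set was called at an adjusted p of 0.05, and a fold change of 2 was used as a second threshold for counts. The comparisons were inoculated minus mock at each time as the mean of 8 cultivars and in each cultivar, the difference of that effect between the times, 120 h minus 72 h in mock plants, an F test among cultivars in mock plants, an F test among the infection effects of the cultivars at each time, and the infection effects of CONRAD and V710370 minus that of SLOAN. CONRAD and V710370 were chosen before the data were examined because breeders know them as sources of quantitative resistance, and SLOAN as a susceptible cultivar; the sources used here do not state this. *P. sojae* probe sets were quantile-normalized among themselves and fitted in the same way. Their comparisons over time and among cultivars used the 64 inoculated arrays only.

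Gene lists were written before the data were examined, from soybean gene symbols and names. They cover isoflavonoid and glyceollin synthesis, pathogenesis-related proteins, glutathione transferases, WRKY factors, jasmonate and lipoxygenase, salicylate signalling, ethylene, lignin and peroxidases, protease inhibitors, heat shock proteins, aquaporins, cytosolic ribosomal proteins, cell wall loosening, sugar transport, photosynthesis, nodule proteins, seed storage proteins, histones and cell cycle, and disease resistance homologues. A list of receptor-like kinases and all *P. sojae* lists, from elicitins and effectors to tubulin and actin, had no named members. Another 14 lists were written from the symbols of the annotation, before any group difference was computed but after the tables had been opened. Lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, with the brightest probe set of each gene and all tested soybean probe sets as background, adjusted over all lists of a time; the test was repeated with an estimated correlation.

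Named genes followed a rule fixed before the data were examined. For infection at each time it takes the 10 largest rises and 10 largest falls past the threshold with the same direction in all 8 cultivars. For each list it takes the 3 members with the smallest adjusted p at 120 h. For the effects of time it takes the 5 highest and 5 lowest, for tests among cultivars the 5 smallest p, and for *P. sojae* the 10 highest and 10 lowest. Other genes named were chosen after their values were seen; in the lists these are OLPa, PR-10, G4DT, IFR, CHS1, IFS2, 4CL4, 4CL, 4CL2, GSTU47, WRKY25, AOS1, AOS2, AOC3, AOC4, LOX9, LOXB1, ACS1, PAD4, MYB29 and MYB112.

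The *P. sojae* signal of an array was the mean log2 value of all *P. sojae* probe sets minus the mean of the nematode probe sets, and the *P. sojae* share was the percentage of the linear signal above the nematode median in *P. sojae* probe sets. Differences of this signal were tested by permutation, exactly within a cultivar (70 splits of 4 against 4, smallest possible p 0.0286) and otherwise with 100000 resamples; 11 such tests and 12 correlations with list scores were each adjusted together.

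The replicate letters pair the arrays: the mean deviations of a letter in mock and inoculated plants correlated at 0.32 to 0.58 in all 8 combinations of letter and time, above the minimum of 0.1 set before the data were examined. Pairs within a cultivar and time did so in 55 of 64 cases (median r = 0.25, lowest -0.02). A fit with the letters as a block is given where it moves a count by more than 1.5 times. As checks of identity, the highest correlation of 2 arrays was 0.992, 0 columns were identical, 128 of 128 arrays lay closest to their own cultivar, and 127 of 128 lay on their treatment's side of the first principal component, which held 59.0% of the variance.

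The alternatives tried were centring or quantile-normalizing the soybean probe sets alone, other detection filters, replicate and title-number blocks, the *P. sojae* signal as a covariate, a variance trend, leaving out each replicate letter, and others added after the data were seen, which the closing section names. The pipeline was tested on simulated data: of probe sets with an added log2 change of 1, it recovered 100% for infection at 120 h, 80.6% for infection in CONRAD, 65.7% for CONRAD against SLOAN and 62.7% for the F test of cultivar and infection at 120 h, and it called 0.04% of unchanged probe sets for infection at 120 h. The simulated noise was independent for each probe set and array, without letter effects or added *P. sojae* RNA. These rates therefore check the code and do not give the rate of false calls in the real arrays. There, 165 of 415 detected nematode probe sets were called for infection at 120 h. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and, in R, data.table (version 1.17.8). The number of arrays limits the precision of each value.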

Results

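The series asked how soybean and *P. sojae* express their genes during infection of cultivars that vary in quantitative resistance. Inoculated plants were first compared with mock plants of the same cultivar and time.

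PR1-1 (synonym PR1a), a gene of a pathogenesis-related protein, rose in infected plants from 5.90 ± 1.59 to 13.76 ± 0.21 at 72 h and from 4.59 ± 1.5 to 13.56 ± 0.23 at 120 h (log2 mean ± SD, n = 32 arrays per treatment). The inoculated level lies close to the highest value of an array, 13.92 ± 0.09 (SD, n = 64), and 14 of 32 mock arrays were above background at 120 h, so no fold is given. PR1-7 rose by 5.97 and 6.80 on the log2 scale at the 2 times (SE 0.12), PR10 by 5.08 and 6.12 (SE 0.11), and the osmotin-like OLPb by 3.82 and 4.39 (SE 0.09). LOC100500525 rose by 6.56 and 7.62 (SE 0.14), LOC100778056, whose synonym is CYP82A4, by 6.43 and 7.29 (SE 0.16), and LOC100306165 by 6.81 at 120 h (SE 0.13). The unnamed probe set GmaAffx_90538_1_A1_s_at rose by 6.57 and 7.95 (SE 0.15). The deepest falls included GmaAffx_62750_2_S1_at, with -6.29 and -6.18 (SE 0.10), LOC778029, with -4.97 and -5.54 (SE 0.29), and LOC100789249, with -4.11 and -4.24 (SE 0.21). SWEET17, a member of the SWEET family of sugar transporters, fell by 3.52 at 72 h and fell by 4.54 at 120 h (SE 0.12), and CYSP2 fell by 3.96 at 120 h (SE 0.17). Each of these moved the same way in all 8 cultivars. Many mock values of these rises lay below background, and with such values set to it the rises were 5.24 and 5.91 for PR1-7, 5.66 and 6.48 for LOC100500525, 6.40 and 7.76 for GmaAffx_90538_1_A1_s_at, and at 120 h 5.11 for PR10 and 6.89 for LOC100778056. In the same way LOC778029 came to -4.29 and -5.28. Second probe sets moved less for PR1-1 (3.30 and 3.57), for LOC778029 (-1.23 and -2.82) and for SWEET17 (-1.32 and -2.27).

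Of 27289 soybean probe sets, 22480 changed at 72 h (10337 higher, 12143 lower) and 22874 at 120 h (11822 higher, 11052 lower). The majority at 120 h depends on scaling: 10143 were higher and 12919 lower with median centring, and 10080 and 13053 with quantile normalization of the soybean probe sets. By at least 2-fold, 2245 rose and 1624 fell at 72 h, and 2676 rose and 1892 fell at 120 h. The same direction was called at both times for 19841 probe sets (72.7%), and opposite directions for 501. Called in every cultivar were 3200 rises and 2786 falls at 72 h, and 3446 rises and 2571 falls at 120 h. With 32 arrays on each side small differences pass the test, also ones that need not be changes of soybean expression. Nematode probe sets, the background, were called in 187 of 415 cases at 72 h, 173 higher and 14 lower, with a median difference of 0.08. The median of all nematode probe sets was 2.99 ± 0.05 in mock and 3.04 ± 0.04 in inoculated arrays (SD, n = 64 each). The background was thus shifted between the treatments, and soybean calls of this size may hold such a shift.

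All 7 measured pathogenesis-related genes rose at both times, with medians of 3.84 at 72 h and 6.12 at 120 h. The list passed camera (adjusted p = 2.2e-07 and 5.8e-07), but not with an estimated correlation (adjusted p = 0.0506 and 0.0686 with an estimated correlation). The thaumatin-like OLPa rose by 2.88 and 4.00 (SE 0.12), PR-10 by 3.84 and 6.17 (SE 0.16), and CHIA1 by 3.64 and 4.76 (SE 0.11). All 7 were also called when adjusted over the list alone.

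Genes of isoflavonoid and glyceollin synthesis, the route to the soybean phytoalexins, rose in 20 of 23 cases at 72 h and 21 of 23 at 120 h, with medians of 2.18 and 2.56. Camera called the list at both times (adjusted p = 4.0e-11 and 4.0e-10), but not with an estimated correlation (adjusted p = 0.0689 and 0.109 with an estimated correlation). The glyceollin prenyltransferase gene G4DT rose by 4.17 and 5.62 (SE 0.14), the isoflavone reductase gene IFR by 4.22 and 4.66 (SE 0.12), and the chalcone synthase gene CHS1 by 3.23 and 4.25 (SE 0.16). The isoflavone synthase gene IFS2 rose by 2.80 and 3.40 (SE 0.09), 4CL4 by 3.48 and 3.88 (SE 0.10), CYP93A1, which encodes dihydroxypterocarpan 6a-hydroxylase, by 3.27 and 3.75 (SE 0.09), and the chalcone reductase gene CHR5 by 2.78 and 3.23 (SE 0.08). Within the list 4CL fell by 0.39 at 72 h and 4CL2 fell by 0.54 at 120 h. Adjusted over the list alone, 21 members were called at 72 h and 22 at 120 h. CHIA1 is matched by both of these lists.

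**Figure D1:**
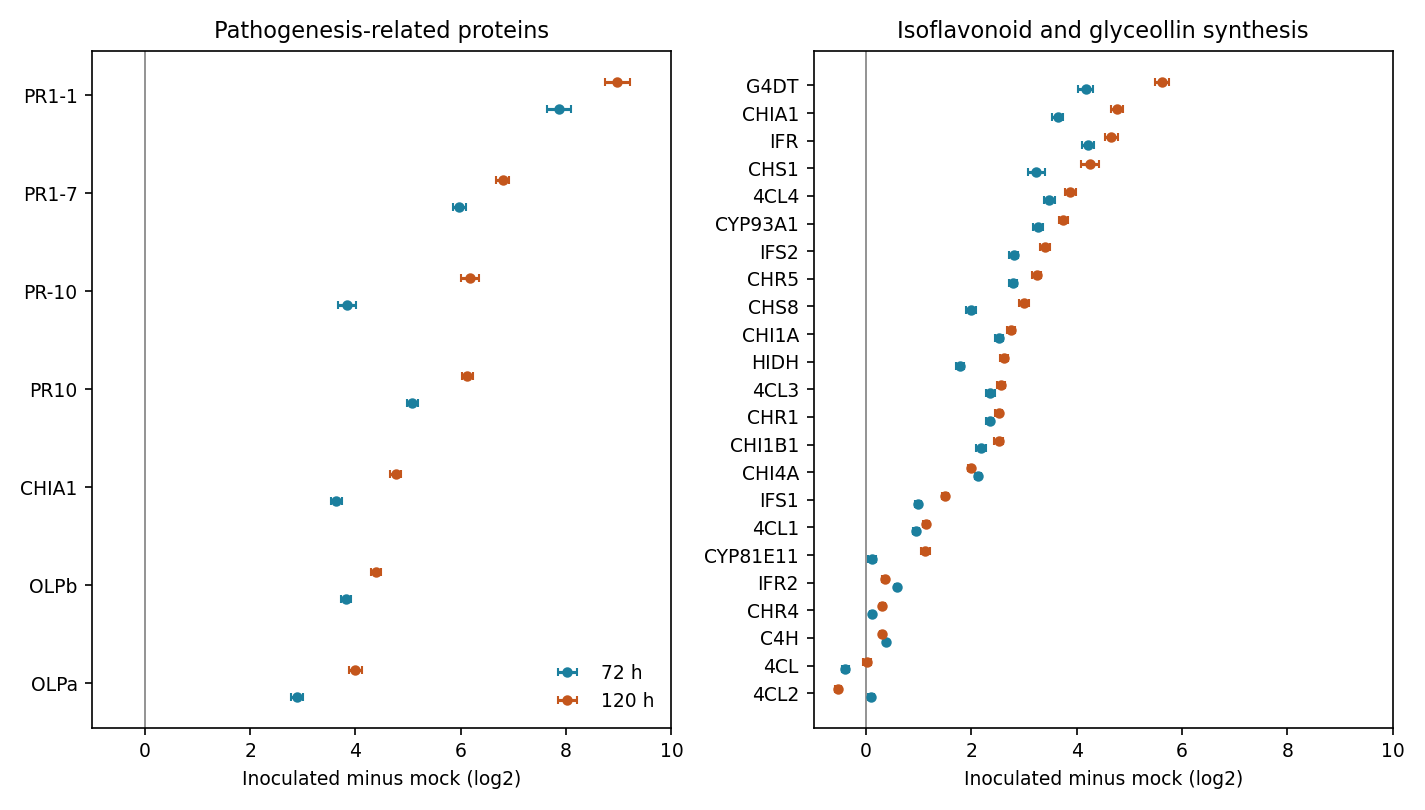
Difference between inoculated and mock plants (log2, mean of 8 cultivars with SE) for each measured gene of the pathogenesis-related and isoflavonoid lists at 72 and 120 h. G4DT stands at 4.17 and 5.62, and 4CL2 is the lowest at 120 h with -0.54.

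Glutathione transferase genes rose in 16 of 22 cases at each time and fell in 4 at 72 h and 3 at 120 h, with medians of 0.90 and 1.00. Camera called them (adjusted p = 0.00142 and 0.000394), but not with an estimated correlation (adjusted p = 0.15 and 0.109 with an estimated correlation). GSTU9 rose by 2.60 and 3.79 (SE 0.08), GST3 by 1.66 and 2.33 (SE 0.06) and GSTU27 by 2.06 and 1.83 (SE 0.05), while GSTU47 changed by -2.17 and -2.35 (SE 0.07). WRKY transcription factor genes rose in 32 of 48 cases at each time and fell in 14 and 13, with medians of 0.48 and 0.47. Camera called them (adjusted p = 0.00392 and 0.0274), but not with an estimated correlation (adjusted p = 0.343 and 0.458 with an estimated correlation). WRKY6 rose by 3.30 and 3.84 (SE 0.12), WRKY53 by 3.09 and 3.18 (SE 0.08) and WRKY25, below background in all mock arrays, by at least 2.55 and 1.45, while WRKY24 changed by -1.27 and -1.43 (SE 0.05). Adjusted over the list alone, 20 and 19 glutathione transferases and 47 and 45 WRKY genes were called at the 2 times.

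Jasmonate and lipoxygenase genes rose in 8 of 10 cases at 72 h, where LOXB1 changed by -0.08, and in 6 of 10 at 120 h, with medians of 0.87 and 0.64. Camera called the list at 72 h (adjusted p = 0.0429) but not at 120 h (adjusted p = 0.126), and at neither time with an estimated correlation (adjusted p = 0.441 and 0.458 with an estimated correlation). AOC6, an allene oxide cyclase gene, rose by 1.35 and 1.31 (SE 0.10), and the vegetative storage protein gene VSPA by 0.56 and 1.73 (SE 0.11). LOX7 rose by 0.62 and 1.45 (SE 0.10) and LOX9 by 0.98 and 1.49 (SE 0.12). Adjusted over the list alone, 9 members were called at 72 h and 6 at 120 h. Against a background of genes with a symbol of their own, a setting chosen after the data were seen, camera kept the pathogenesis-related list (adjusted p = 0.000132 at 72 h and 0.000179 at 120 h), the isoflavonoid list (adjusted p = 1.1e-06 and 3.3e-06) and, at 120 h only, the glutathione transferases (adjusted p = 0.0535 and 0.0222). It did not keep the WRKY list (adjusted p = 0.0927 and 0.287) or the jasmonate list (adjusted p = 0.202 and 0.406).

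Salicylate genes rose in 3 of 4 cases at both times (medians 0.51 and 0.76, camera adjusted p = 0.151 and 0.220), among them EDS1-2 by 0.62 and 1.01 (SE 0.06), NDR1A by 0.40 and 0.51 (SE 0.06) and NDR1b by 1.22 and 1.05 (SE 0.13). PAD4 stood at 0.14 and -0.01 and was not called. Of 6 ethylene genes 2 rose and 3 fell at each time (medians -0.24 and -0.14, adjusted p = 0.937 and 0.861), and at 72 h camera pointed up while the median was negative. The receptor gene ETR2 rose by 1.76 and 2.07 (SE 0.07), ACS1 by 2.74 and 1.45, while ERF6 changed by -0.44 and -0.77 (SE 0.07) and EIN4 changed by -0.53 and -0.57 (SE 0.05). Of 4 lignin and peroxidase genes 2 rose at 72 h and 3 at 120 h, and 1 fell (medians 0.65 and 0.57, adjusted p = 0.359 and 0.418). PRX4 rose by 1.39 and 1.94 (SE 0.05), CCR by 1.21 and 0.92 (SE 0.06), and PRX2 changed by -1.80 and -1.67 (SE 0.07). Adjusted over each list alone, the calls numbered 3 and 3 for salicylate, 5 and 5 for ethylene and 3 and 4 for lignin genes.

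Heat shock genes rose in 3 of 5 cases at 72 h and 4 of 5 at 120 h and fell in 1 (medians 0.34 and 0.79, camera adjusted p = 0.452 and 0.233). HSP90A1 rose by 0.76 and 1.54 (SE 0.10) and HSP90-1 by 0.34 and 0.69 (SE 0.06). HSP23.9 stood at 0.10 at 72 h, where it was not called, and rose by 0.88 at 120 h (SE 0.10). Aquaporin genes fell in 11 of 17 cases at 72 h and 9 at 120 h and rose in 5 and 7 (medians -0.35 and -0.18, adjusted p = 0.288 and 0.544). PIP1-4 changed by -1.53 and -1.54 (SE 0.06), PIP2-4 changed by -0.65 and -0.63 (SE 0.04), and NIP1-8 rose by 1.55 and 1.84 (SE 0.09). Sugar transport and sucrose cleavage genes rose in 4 of 9 cases at each time and fell in 5 and 4 (medians -0.22 and 0.01, adjusted p = 0.845 and 0.861). SWEET29 rose by 2.45 and 3.09 (SE 0.10) and SWEET34 by 1.71 and 2.65 (SE 0.09). All 4 ribosomal protein genes rose (medians 0.22 and 0.26, adjusted p = 0.186 and 0.164), RPL37 by 0.26 and 0.37, RPS6 by 0.22 and 0.28 and RPL2 by 0.22 and 0.24 (SE 0.03 to 0.04). Adjusted over each list alone, the calls at the 2 times numbered 4 and 5 heat shock, 16 and 16 aquaporin, 9 and 8 sugar and 4 and 4 ribosomal genes.

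Protease inhibitor genes rose in 1 of 3 cases at each time and fell in 2 at 72 h and 1 at 120 h (medians -0.34 and 0.04, adjusted p = 0.876 and 0.603), and at 72 h camera pointed up while the median was negative. BBI-1, a Bowman-Birk inhibitor gene, rose by 2.54 and 3.32 (SE 0.10), and BBI-2 changed by -0.51 and -0.96 (SE 0.13). CYSTATIN fell by 0.34 at 72 h and stood at 0.04 at 120 h, not called (SE 0.03). Of 4 cell wall loosening genes 2 rose and 2 fell at 72 h, and 1 rose and 1 fell at 120 h (medians -0.05 and 0.12, adjusted p = 0.845 and 0.861). EXP1 rose by 0.44 and 0.54 (SE 0.10) and EXP4 changed by -1.30 and -0.36 (SE 0.15), while EXP2 fell by 0.39 at 72 h and stood at 0.11 at 120 h, not called (SE 0.06, adjusted p = 0.069; adjusted p = 0.041 with the letters as a block). Adjusted over each list alone, the calls numbered 3 and 2 protease inhibitor and 4 and 2 cell wall genes. The medians of the sugar and protease inhibitor lists at 120 h turn negative when soybean probe sets are centred on their median (-0.08 and -0.04).

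Lists with fewer than 3 measured genes were not tested as lists. The chlorophyll-binding protein gene CAB3 changed by -1.99 and -1.89 (SE 0.10), while the photosystem gene PSAD rose by 0.50 and 0.70 (SE 0.04); its other probe sets fell, to as low as -1.58 and -1.69. The nodulin genes ENOD40B and NOD33 changed by -0.97 and -0.45 at 72 h and by -1.76 and -0.12 at 120 h (SE 0.09 and 0.03). CYP34, a cyclophilin-type symbol and the only match to the seed storage list, fell by 0.15 at 72 h and stood at 0.00 at 120 h (SE 0.03). CDC48, the only match to the cell cycle list, stood at -0.04 at 72 h and rose by 0.29 at 120 h (SE 0.03). The only matches to disease resistance homologues were the ribosomal protein genes RPS13, which rose by 0.10 and 0.20, and RPS6. Adjusted over each list alone, 2 photosynthesis, 2 nodule and 2 disease resistance matches were called at each time, CYP34 only at 72 h and CDC48 only at 120 h.

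The next comparison asked whether the infection effect differed between the 2 times. LOC547748 had an infection effect that was higher at 120 h by 3.07 (SE 0.20, adjusted p = 2.5e-24; second probe set 2.67; n = 32 arrays per treatment and time). The effect on LOC547636 was lower at 120 h, at -2.23 (SE 0.23, adjusted p = 4.5e-14; second probe set -1.81), with inoculated levels of 8.76 and 6.22 and no mock array above background at 120 h, as was that on LOC100800305, at -2.23 (SE 0.14, adjusted p = 5.0e-26), and on 1 probe set of LOC100800404, at -2.13 (SE 0.17), while its other probe sets stood at 0.12 and 0.16. All 7 pathogenesis-related genes had a higher effect at 120 h (median 1.11), led by PR-10 at 2.33 (adjusted p = 6.7e-15). Isoflavonoid genes had a higher effect at 120 h in 16 of 23 cases and a lower one in 2 (median 0.41), G4DT among them at 1.45 (adjusted p = 2.1e-09). Among jasmonate genes the effect on VSPA was higher at 120 h by 1.17, and the effects on AOC4, AOC3, AOS1 and AOS2 were lower, at -1.17, -0.93, -0.76 and -0.69. WRKY genes were divided, with 14 higher and 13 lower. In inoculated plants alone, a comparison added after the data were seen, 2 of 7 pathogenesis-related genes were higher at 120 h than at 72 h (median 0.03), PR10 stood at 0.05 (adjusted p = 0.752) and OLPa at 0.03 (adjusted p = 0.854). PR1-1 and PR-10, at 13.56 and 13.25 in inoculated plants at 120 h, lie close to the array maximum, where a further rise can be missed. Of the isoflavonoid genes 16 of 23 were lower and 2 higher there (median -0.28), G4DT among the lower ones at -0.48 (adjusted p = 0.00276), so the higher effects of this list at 120 h rest on lower mock levels, given below. VSPA was higher there by 0.54, AOC3, AOS1 and AOS2 were lower, at -0.89, -0.54 and -0.53, and AOC4 stood at -0.30 (not called). The effect differed between the times for 9562 probe sets, 6738 higher and 2824 lower at 120 h, of which 373 and 107 differed by at least 2-fold. The share of higher ones, 70.5%, came to 43.3% after median centring and 48.8% after quantile normalization of the soybean probe sets, and the count to 2319 in the 4 cultivars with the least added *P. sojae* RNA, a setting chosen after the data were seen.

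In mock plants, gene levels were compared between the times. LOC778029 rose from 8.60 ± 1.42 at 72 h to 10.64 ± 1.45 at 120 h (log2 mean ± SD, n = 32; difference 2.03, SE 0.29, adjusted p = 3.9e-09). LOC100527097 fell from 8.37 ± 0.66 to 5.73 ± 1.36 (difference -2.63, SE 0.16, adjusted p = 2.2e-27), LOC100794600 by a log2 difference of -2.52 (SE 0.13) and LOC100500599 by one of -2.47 (SE 0.16). Of the pathogenesis-related genes 6 of 7 were lower at 120 h (median -1.0), with PR-10 at -2.36 (adjusted p = 9.3e-24). Of the isoflavonoid genes 21 of 23 were lower and 1 higher (median -0.69), with G4DT at -1.94 (adjusted p = 1.6e-22). In total 14788 probe sets differed between the times, 2802 higher and 11986 lower at 120 h, of which 75 and 258 by at least 2-fold. The median of all tested soybean probe sets was -0.09, and centring moved it to 0.02 and the share of higher calls from 18.9% to 58.6%, with quantile normalization giving 51.6%. The *P. sojae* share of the mock arrays was 4.19% ± 1.98 at 72 h and 7.30% ± 4.16 at 120 h (SD, n = 32), and in the 4 cultivars with the least added *P. sojae* RNA the count was 5214.

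**Figure D2:**
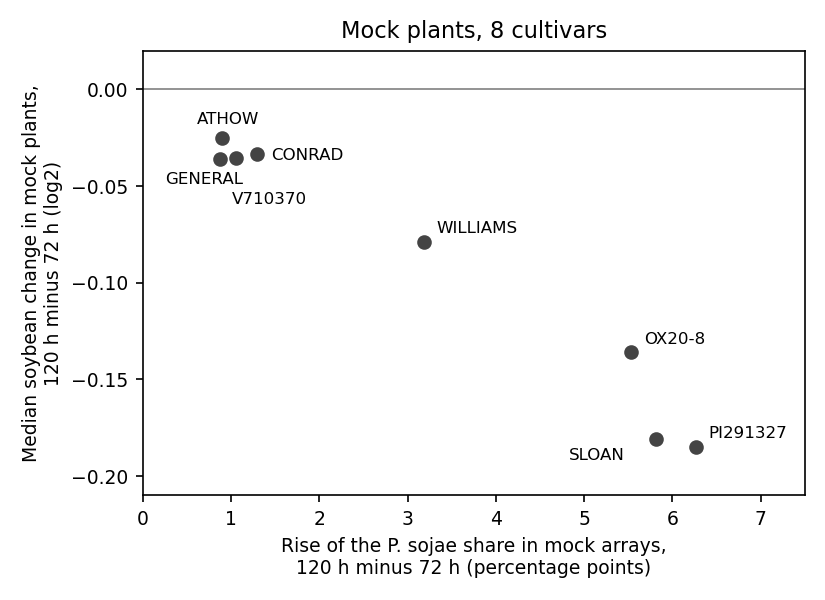
Median log2 difference of all tested soybean probe sets between 120 h and 72 h in mock plants, against the rise of the *P. sojae* share of the mock arrays in percentage points, with 1 point per cultivar. CONRAD, with a rise of 1.29, lies at -0.03 and PI291327, with a rise of 6.26, at -0.18.

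Gene levels were next compared among the cultivars without infection. LOC100305823 stood at 6.81 ± 0.47 in PI291327 and 7.55 ± 0.53 in V710370 (log2 mean ± SD, n = 8 mock arrays) and was not above background in any mock array of the other 6 cultivars (adjusted p = 7.0e-78). LOC100499730 stood at 7.68 ± 0.34 in OX20-8 and 7.56 ± 0.28 in PI291327 and was not above background elsewhere. LOC100527650 was above background in 0 of 8 mock arrays in CONRAD and 3 of 8 in SLOAN, and stood between 9.16 and 9.98 elsewhere. The unnamed Gma_5783_2_S1_s_at was not above background in PI291327 and stood at 11.83 ± 0.12 in CONRAD, the highest (adjusted p = 1.2e-100). Levels differed among cultivars for 23153 of 27289 probe sets. The mock arrays also differed by cultivar in their *P. sojae* share. Its mean ran from 2.34% in CONRAD to 6.93% in SLOAN at 72 h, and from 3.22% in GENERAL to 12.8% in SLOAN at 120 h. The count stayed within 1.5 times with median centring, but how much of it comes from the added RNA was not tested. A probe can also bind worse where a cultivar's sequence differs from the array's, and cultivar sequences were not examined here.

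Whether infection acted differently in the 8 cultivars was tested at each time. LOC732592 was not above background in any mock array and rose at 72 h by at least 3.24 in CONRAD, 3.18 in OX20-8, 3.07 in PI291327, 3.90 in SLOAN, 2.07 in V710370 and 2.62 in WILLIAMS. In ATHOW and GENERAL it was not above background in inoculated arrays either (n = 4 arrays per group, adjusted p = 4.6e-32 for the difference among cultivars). These values are from 1 of its probe sets, and the others rose less. As measured, the rise in V710370 at 72 h was 3.21 for this probe set and 2.80 and 2.26 for the others. LOC100795212, also below background in all mock arrays, rose at 120 h by at least 2.98 in OX20-8 and 1.48 in SLOAN (adjusted p = 2.2e-31), and LOC100500303 by at least 2.68 in OX20-8 and 0.96 in SLOAN (adjusted p = 2.1e-28). In the other cultivars at most 2 of 4 inoculated arrays were above background for these 2 genes. GmaAffx_26983_1_S1_at fell at 120 h by at least 5.60 in OX20-8 and 4.67 in SLOAN, to below background, and changed by -3.73 in WILLIAMS (SE 0.30; adjusted p = 6.3e-30). GmaAffx_81147_1_S1_at was above background only in mock SLOAN plants, at 6.93 ± 0.74 and 6.47 ± 0.85 (SD, n = 4), and fell there with infection by at least 2.67 and 2.28. The effect differed among cultivars for 9761 probe sets at 72 h and 16559 at 120 h. Each effect is taken against mock arrays whose mean *P. sojae* share differed by cultivar. At 72 h it ran from 2.34% in CONRAD to 6.93% in SLOAN, and at 120 h from 3.22% in GENERAL to 12.8% in SLOAN. Both counts stayed within 1.5 times with median centring, but the part that the added RNA has in them was not tested. A refit without replicate Y called 4633 at 72 h and 11037 at 120 h, and refits without replicate V or W called 6165 and 5676 at 72 h.

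**Figure D3:**
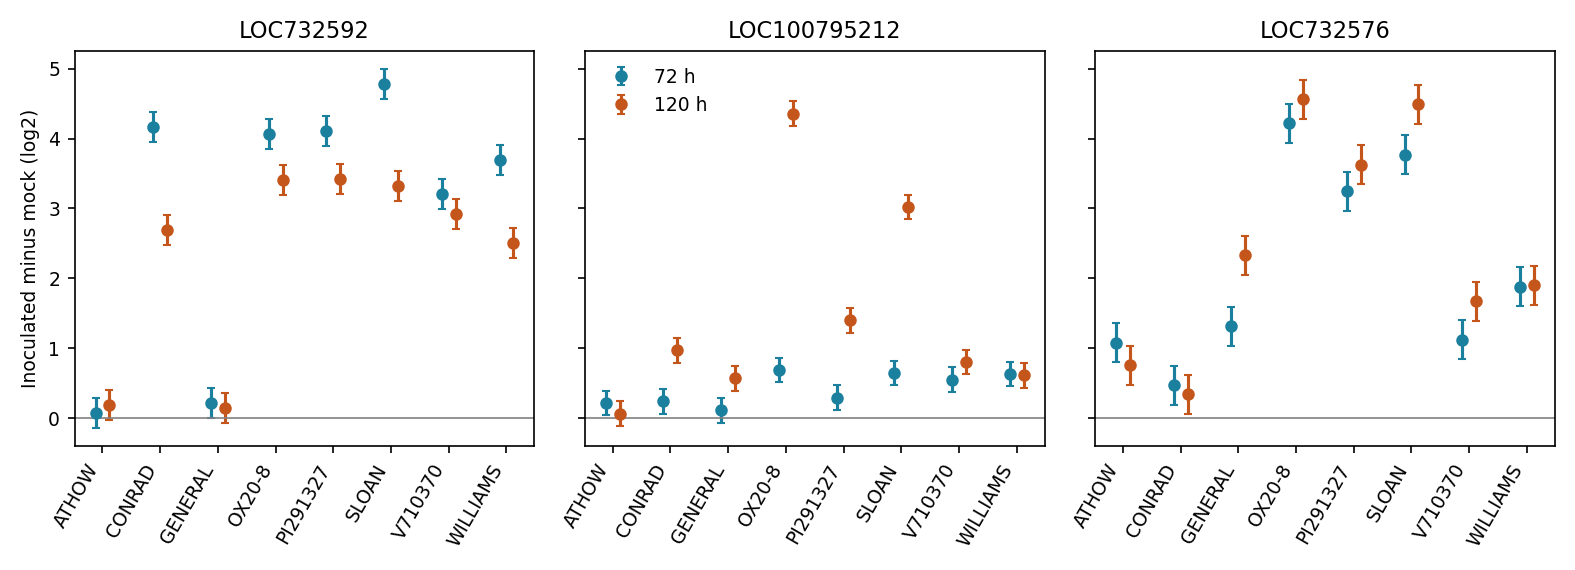
Difference between inoculated and mock plants (log2, with SE, n = 4 arrays per group) of LOC732592, LOC100795212 and LOC732576 in each cultivar at 72 and 120 h, as measured, including values below background. LOC732576 stands at 0.47 in CONRAD and 3.77 in SLOAN at 72 h.

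The pathogenesis-related genes rose in 7 of 7 cases in every cultivar at both times. Their median rise at 72 h ran from 3.41 in ATHOW to 4.36 in WILLIAMS, and at 120 h from 5.06 in ATHOW to 6.66 in PI291327, and the effect differed among cultivars for 1 member at 72 h and 6 at 120 h. The isoflavonoid genes had medians at 120 h between 1.86 in ATHOW and 3.38 in OX20-8, and 7 and 18 of the 23 differed among cultivars at the 2 times. Jasmonate and lipoxygenase genes rose at 72 h in 9 of 10 cases in OX20-8 (median 1.75), 8 in PI291327 (1.46), 8 in SLOAN (1.70) and 6 in CONRAD (0.89), and in 4 of 10 in ATHOW (0.11) and GENERAL (0.28) and 1 of 10 in V710370 (0.25) and WILLIAMS (0.29). The effect on 6 of these 10 differed among cultivars at 72 h and on 7 at 120 h.

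Each cultivar was also compared with its own mock plants. At 72 h, SLOAN had 17174 called probe sets, OX20-8 17098, PI291327 16766, CONRAD 14931, WILLIAMS 13060, GENERAL 11626, ATHOW 11415 and V710370 10374. At 120 h, OX20-8 had 19082, SLOAN 18167, PI291327 17392, CONRAD 14931, V710370 14931, WILLIAMS 14652, GENERAL 12344 and ATHOW 9721. A refit without replicate V called 6658 in ATHOW at 72 h, 6108 in ATHOW at 120 h and 5997 in V710370 at 72 h, and a refit without replicate W called 6400 in ATHOW at 120 h. The share of higher calls moved by more than 10 points with median centring in WILLIAMS, from 58.7% to 40.03% at 72 h and from 68.9% to 39.7% at 120 h. At 120 h it also moved in ATHOW, from 59.6% to 44.1%, in PI291327, from 58.8% to 42.3%, and in SLOAN, from 62.6% to 43.1%. Centring moved the median of all genes from 0.15 to -0.10 in WILLIAMS, from 0.16 to -0.11 in SLOAN and from 0.10 to -0.10 in PI291327 at 120 h, from 0.06 to -0.10 in WILLIAMS at 72 h, and from -0.15 to -0.04 in OX20-8 at 72 h.

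**Figure D4:**
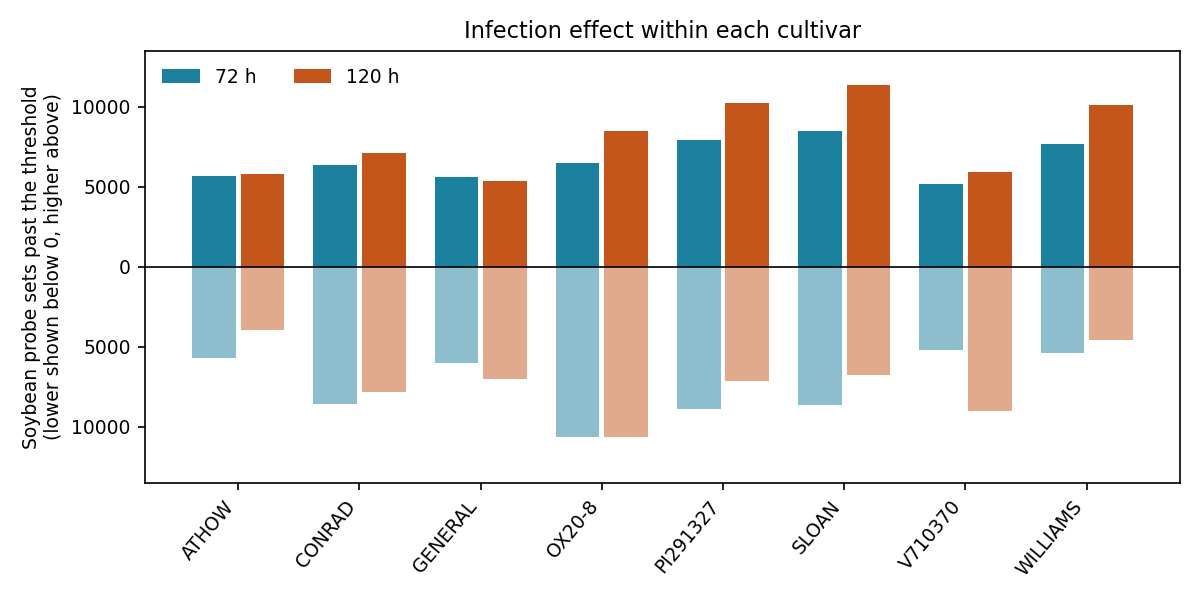
Number of soybean probe sets higher (above 0) and lower (below 0) in inoculated than in mock plants in each cultivar at 72 and 120 h. Bars are counts past the test, from 9721 in total in ATHOW to 19082 in OX20-8 at 120 h.

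CONRAD and V710370 were compared with SLOAN for the effect of infection. LOC732576 rose in SLOAN by 3.77 at 72 h and 4.49 at 120 h, but stood at 0.47 and 0.34 in CONRAD, where it was not called and 1 and 2 of 4 mock arrays were above background (SE 0.28, n = 4 arrays per group), a difference of -3.30 (SE 0.39, adjusted p = 2.5e-09) and -4.15 (adjusted p = 6.7e-14). GmaAffx_82603_1_S1_at was not above background in SLOAN in either treatment, and in V710370 it rose by 3.72 at 72 h, with mock values below background set to it, and by at least 4.04 at 120 h (adjusted p = 1.4e-15 and 8.7e-21 for the difference of the effects). Gma_919_1_A1_at was not above background in SLOAN either, and in V710370 it fell at 120 h from 6.06 ± 0.48 to below background, by at least 1.82 (adjusted p = 1.7e-24 for the difference). GmaAffx_81147_1_S1_at was below background in all arrays of CONRAD and V710370, where no fall could be seen.

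Between CONRAD and SLOAN, 241 probe sets differed in the infection effect at 72 h (72 higher, 169 lower in CONRAD; 809 with the letters as a block) and 4077 at 120 h (366 higher, 3711 lower; 6198 with the block). Between V710370 and SLOAN, 3605 differed at 72 h (1635 higher, 1970 lower; 6075 with the block) and 7116 at 120 h (585 higher, 6531 lower). With letters and title numbers as blocks the counts at 72 h were 528 and 1923 (27.3% and 35.5% higher). With the *P. sojae* signal as a covariate they were 2958 and 7194, and the share of higher ones turned from 29.9% to 71.3% for CONRAD and from 45.4% to 66.6% for V710370. The split at 120 h depended on scaling: the higher share in CONRAD moved from 8.98% to 59.9% of 2360 calls with centring and to 45.0% of 1766 with quantile normalization, and in V710370 from 8.22% to 63.0% of 3716 and to 45.0% of 2919. At 72 h the higher share in CONRAD moved from 29.9% to 58.5% with centring and to 53.4% with quantile normalization. Centring moved the median difference of all genes at 120 h from -0.19 to 0.06 for CONRAD and from -0.27 to 0.06 for V710370. Refits without a replicate letter called fewer: for CONRAD at 72 h 155 without V, 57 without W, 74 without Y and 122 without Z, and at 120 h 1593 without W, 2512 without Y and 2180 without Z; for V710370 at 72 h 1029 without W, 1888 without Y and 1674 without Z, and at 120 h 3756 without W and 4562 without Z.

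The amount of *P. sojae* RNA in the infected tissue was compared among cultivars and between times. The *P. sojae* share of the array signal was highest in OX20-8, at 5.07% ± 1.52 at 72 h and 8.25% ± 4.36 at 120 h (SD, n = 4), and lowest in GENERAL at 72 h (1.26% ± 0.22) and ATHOW at 120 h (1.25% ± 0.18). SLOAN stood at 2.41% ± 0.07 and 3.50% ± 0.30, CONRAD at 1.57% ± 0.42 and 1.90% ± 0.70, and V710370 at 1.30% ± 0.20 and 2.54% ± 0.76. GENERAL stood at 2.18% ± 0.79 at 120 h, ATHOW at 1.27% ± 0.21 at 72 h, PI291327 at 1.92% ± 0.57 and 2.64% ± 0.83, and WILLIAMS at 1.70% ± 0.48 and 1.79% ± 0.54. The 4 OX20-8 arrays had a *P. sojae* signal above that of all other arrays at each time. Signals differed among cultivars at both times (F = 15.3 and 10.7, permutation p = 1e-05, the smallest possible, adjusted p = 5.5e-05). From 72 to 120 h the mean signal of the 8 cultivars rose by 0.10 on the log2 scale (permutation p = 6e-05, adjusted p = 0.00022). Within a cultivar, SLOAN gained 0.13 and V710370 0.17 (exact p = 0.0286, the smallest possible, adjusted p = 0.0629), GENERAL 0.15 (exact p = 0.0571), OX20-8 0.21 (exact p = 0.20), PI291327 0.10 (exact p = 0.257), CONRAD 0.04 (exact p = 0.543), WILLIAMS 0.02 (exact p = 0.686) and ATHOW 0.01 (exact p = 0.743), none of which passed adjustment. Permuted within the replicate letters, GENERAL, OX20-8, PI291327, SLOAN and V710370 each had exact p = 0.125, the smallest possible of 16 permutations (adjusted p = 0.172), and the mean of the 8 cultivars had p = 1e-05, the smallest possible (adjusted p = 3.7e-05).

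**Figure D5:**
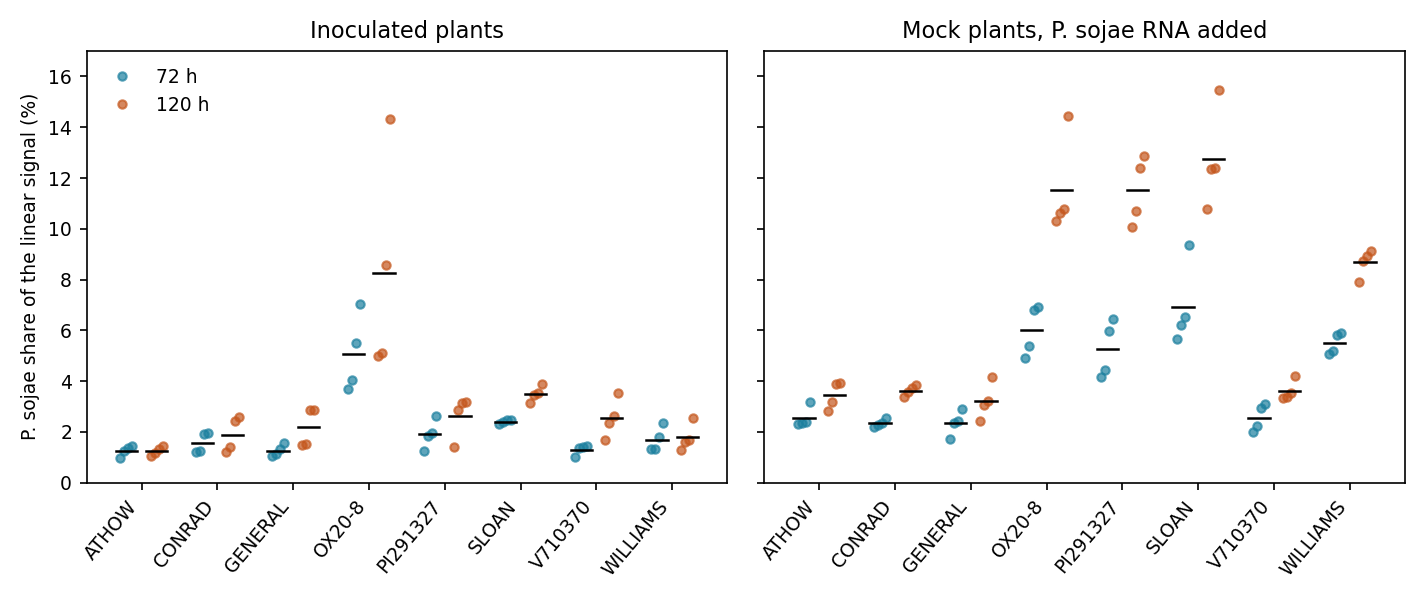
*P. sojae* share of the array signal (percent) in inoculated and mock arrays of each cultivar at 72 and 120 h; points are arrays and bars are means of 4. In inoculated plants OX20-8 is highest, at 5.07% and 8.25%.

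Across the 32 inoculated arrays of a time, the mean level of the pathogenesis-related genes was correlated with the *P. sojae* signal (Pearson's r = 0.44 at 72 h, permutation p = 0.0116, adjusted p = 0.0293; r = 0.47 at 120 h, permutation p = 0.0122, adjusted p = 0.0293; Spearman's rho = 0.55 and 0.65, adjusted p = 0.00194 and 0.00036). After cultivar means were subtracted r was 0.18 at 72 h (adjusted p = 0.425; rho 0.24, adjusted p = 0.226) and 0.47 at 120 h (adjusted p = 0.0293; rho 0.58, adjusted p = 0.00142). With letter means subtracted r at 120 h was 0.42 (adjusted p = 0.0621; rho 0.58, adjusted p = 0.00225), and 0.28 with cultivar and letter means subtracted (adjusted p = 0.189; rho 0.34, adjusted p = 0.0819). For isoflavonoid genes r was 0.33 (adjusted p = 0.0939) and 0.37 (adjusted p = 0.0810), while rho passed, at 0.57 and 0.62 (adjusted p = 0.00146 and 0.00051). With cultivar means subtracted r was 0.15 and 0.16 (adjusted p = 0.432 at both times) and rho 0.17 and 0.30 (adjusted p = 0.362 and 0.12). The mean level of the 2 photosynthesis genes, CAB3 and PSAD, was negatively correlated with the signal (r = -0.67, adjusted p = 0.00036 at 72 h; r = -0.51, adjusted p = 0.0224 at 120 h; rho = -0.69 and -0.66, adjusted p = 0.00036 at both times). With cultivar means subtracted r was -0.35 (adjusted p = 0.0810) and -0.08 (adjusted p = 0.658), and rho -0.45 (adjusted p = 0.0155) and -0.20 (adjusted p = 0.296). With letter means subtracted as well, rho at 72 h was -0.37 and no longer passed (adjusted p = 0.0646). The permutations behind all these p-values exchanged the arrays of a time freely, also after means were subtracted. They treat arrays of 1 cultivar or letter as independent, although the signal differed among cultivars, so the p-values may be too small. The list scores were not corrected for the level of all soybean probe sets. The median of the tested soybean probe sets was 5.85 on the inoculated array with the highest signal, 1.24 (OX20-8, 120 h). It was 6.68 on that with the lowest, 0.21 (ATHOW, 72 h). A negative r can thus arise without a change particular to photosynthesis genes. The PSAD probe set in the score is the one that rose with infection. Without the OX20-8 arrays, a setting chosen after the data were seen, r was 0.58 and 0.70 for the pathogenesis-related genes, 0.64 and 0.61 for the isoflavonoid genes and -0.58 and -0.50 for the photosynthesis genes. With cultivar means subtracted, r for the isoflavonoid genes was 0.46 and 0.42 without these arrays (adjusted p = 0.0188 and 0.0319). It was 0.46 and 0.43 without the 2 arrays farthest from the median signal (adjusted p = 0.0169 and 0.0232). It did not pass with the *P. sojae* share (0.01 and -0.03) or with letter means subtracted as well (-0.12 and -0.002).

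Expression of *P. sojae* in infected plants was compared with that of the mycelium RNA in the mock samples, in each case after normalization among *P. sojae* probe sets. The mycelium values come from RNA added to mock samples, and n counts arrays. How many mycelium cultures gave this RNA was not taken into account, so the spread between cultures may not be measured. The unnamed probe set PsAffx.psHB032xC08f_at rose from 4.39 ± 0.62 in mycelium to 10.10 ± 0.37 in plants at 72 h (log2 mean ± SD, n = 32 arrays), a rise of 5.71, and by 5.53 at 120 h (SE 0.10). PsAffx.psHB025xE14f_at rose by 5.48 and 5.33 (SE 0.18). PsAffx.CL335Contig1_at fell from 9.18 ± 0.11 to 4.12 ± 0.29, a difference of -5.05, and its difference at 120 h was -5.25 (SE 0.05), and PsAffx.CL647Contig1_at changed by -4.99 and -5.13 (SE 0.06). *P. sojae* values below background were not set to it. The lower levels, 4.39 and 4.12, lie close to the background percentile of the deposited values. That percentile was 4.15 ± 0.09 in mock and 4.22 ± 0.08 in inoculated arrays (SD, n = 64 each), so the size of these differences is uncertain. Of 5290 *P. sojae* probe sets, 4274 differed at 72 h (2392 higher, 1882 lower in plants) and 4423 at 120 h (2332 higher, 2091 lower). By at least 2-fold, 228 were higher and 377 lower at 72 h, and 269 higher and 388 lower at 120 h. Between 72 and 120 h in plants 2401 differed (1055 higher, 1346 lower), 30 and 14 of them by at least 2-fold, and a refit without replicate W called 1410. Among the cultivars 3780 differed. With the *P. sojae* signal as a covariate 620 differed among the cultivars and 677 between the times, 54.7% of them higher in place of 43.9%.

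These comparisons describe expression relative to the rest of the *P. sojae* RNA. On the deposited values, where the amount of *P. sojae* RNA also counts, the share of higher calls was 12.4% of 4287 at 72 h in place of 56.0%, 9.47% of 4721 at 120 h in place of 52.7%, and 97.4% of 2855 between the times in place of 43.9%. The medians of all *P. sojae* probe sets on the deposited values were -0.30 at 72 h, -0.54 at 120 h and 0.15 between the times, and 0.05, 0.03 and -0.03 after normalization. Per array between 1493 and 6126 *P. sojae* probe sets lay above the background percentile, which limits what can be seen of weakly expressed *P. sojae* genes, and no *P. sojae* gene group could be tested since the probe sets carry no gene names in the tables used.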

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

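The search of the soybean medians for samples far from the others, the tests of the mock plants over time and of CONRAD and V710370 against SLOAN, and the balanced splits and the splits with cultivar levels removed, were chosen after the results were seen; the tests of the *P. sojae* probe sets and the other splits were written before.

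A sample far from the others of its group was found in 7 of 96 cases, the 32 groups tested for each of 3 measures (*P. sojae* signal, *P. sojae* share and median of the soybean probe sets), and chance alone marks about 1 in 20 groups. The *P. sojae* share of mock ATHOW at 72 h was 3.18% in replicate Z and 2.33% to 2.37% in the others (gap 0.946 of the range), and that of mock OX20-8 at 120 h was 14.4% in replicate W and 10.3% to 10.8% in the others (0.883). The soybean median was 5.16 in mock WILLIAMS at 72 h, replicate V (others 5.51 to 5.55, gap 0.893), 5.10 in mock OX20-8 at 120 h, replicate W (5.28 to 5.31, 0.863), 5.43 in mock PI291327 at 72 h, replicate W (5.54 to 5.56, 0.898), 5.66 in mock GENERAL at 120 h, replicate W (5.54 to 5.56, 0.893), and 5.82 in mock V710370 at 72 h, replicate Z (5.54 to 5.57, 0.880). All 7 are mock arrays.

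A difference between groups under the same contrast was found in these tests. The infection effect differed between 72 and 120 h for 9562 probe sets, and among cultivars for 9761 at 72 h and 16559 at 120 h. Between CONRAD and SLOAN it differed for 241 at 72 h and 4077 at 120 h, and between V710370 and SLOAN for 3605 and 7116.

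A signal appeared in probe sets that no comparison used: 173 of 415 detected nematode probe sets were higher in inoculated than in mock plants at 72 h and 123 at 120 h. Only 1 rose by at least 2-fold at 120 h, HgAffx_3482_1_A1_at, from 4.01 ± 0.31 to 5.60 ± 0.77 (SD, n = 32; difference 1.59, SE 0.12, adjusted p = 2.0e-22).

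Soybean values were mostly lower at 120 h than at 72 h in mock plants. More added *P. sojae* RNA at 120 h could lower them on arrays normalized as a whole. Across the 8 cultivars the rise of the *P. sojae* share and the median log2 difference had r = -0.984 (exact permutation p = 0.000298, rho = -0.83). Both come from the same normalized arrays, and soybean signal is part of the total from which the share is taken. A negative r can thus arise whatever lowered the soybean values, and it does not decide on the cause. The dilution expected from the share alone was at most -0.10 in a cultivar, less than the observed -0.18 in PI291327 and SLOAN, so normalization of the whole array may add to it or the cause may lie elsewhere. The biological explanation, defence genes that fall with time in mock plants, may hold as well: 24 of 29 pathogenesis-related and isoflavonoid members stayed lower after median centring, 2 were higher, and their median was -0.67 against 0.02 for all soybean probe sets. The tests do not separate wounding or handling from development.

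*P. sojae* probe sets at least 2-fold higher in plants than in mycelium RNA at 120 h numbered 269. If soybean RNA of a steady level bound to them, their deposited values could stand high without regard to the *P. sojae* share. Their median slope on the log2 share was 0.937 (quartiles 0.52 and 1.32), against 0.04 for detected nematode probe sets. It was 0.60 for *P. sojae* probe sets at least 2-fold lower in plants and 0.40 for those that changed under 2-fold. *P. sojae* probe sets are part of the share and nematode ones are not, so some of the slope arises by construction. It argues only in part against binding of this kind. For 27 of the 269 the slope was under 0.1. The slope cannot decide on soybean RNA that rises with infection, since the pathogenesis-related genes also correlated with the *P. sojae* signal (rho = 0.55 and 0.65). The normalization among *P. sojae* probe sets might also create such rises: on the deposited values 84.8% of them were called higher, 12 of 269 lower, and the bounds set beforehand leave this undecided.

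Infection effects at 120 h were mostly lower in CONRAD and V710370 than in SLOAN. More added *P. sojae* RNA in the mock SLOAN arrays could account for the uneven split: the *P. sojae* share of mock arrays at 120 h was 12.8% ± 1.96 in SLOAN, 3.63% ± 0.20 in CONRAD and 3.61% ± 0.41 in V710370 (SD, n = 4), higher in SLOAN by 9.12 and 9.14 percentage points (exact permutation p = 0.0286, the smallest possible). Median centring, after which 40.1% and 37.0% of calls were lower in place of 91.0% and 91.8%, takes out any shift of all soybean probe sets by construction and does not test this. A stronger infection of SLOAN may be a biological explanation, and stays open as well: its *P. sojae* signal at 120 h was higher by 0.17 than that of CONRAD and V710370 (exact permutation p = 0.0121, 4 against 8 arrays). How much *P. sojae* RNA was added to each array is not given in the sources used here.

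Other splits of the same arrays tested whether an arbitrary grouping gives as many calls. Chance can be excluded at 1 of 100 splits, the real one being the highest, for infection at 72 h (22480 calls, highest other 15494) and 120 h (22874, 17217), the effect of time on infection (9562, 426), mock time (14788, 3756), cultivars in mock (23153, 706), cultivar and infection at 72 h (9761, 67) and 120 h (16559, 990). The same holds for *P. sojae* in plants against mycelium at 72 h (4274, 2768) and 120 h (4423, 3387), over time (2401, 5) and among cultivars (3780, 54). These splits test chance only. They do not test the added *P. sojae* RNA, which differed by cultivar and time in the mock arrays. Within single cultivars the real split was the highest of 35 in every case. The real counts and highest others at 72 h were 11415 and 6983 in ATHOW, 14931 and 7862 in CONRAD, 11626 and 6125 in GENERAL, 17098 and 10708 in OX20-8, 16766 and 10881 in PI291327, 17174 and 9217 in SLOAN, 10374 and 6512 in V710370, and 13060 and 6901 in WILLIAMS. At 120 h they were 9721 and 5749 in ATHOW, 14931 and 9695 in CONRAD, 12344 and 4468 in GENERAL, 19082 and 13183 in OX20-8, 17392 and 11213 in PI291327, 18167 and 11492 in SLOAN, 14931 and 7581 in V710370, and 14652 and 6636 in WILLIAMS.

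Chance cannot be excluded by these splits for the number of gene lists, as 11 of 100 splits gave at least the real 9 at 72 h (highest other 11) and 8 of 100 at least the real 11 at 120 h (highest other 14). Nor can it for CONRAD against SLOAN at 72 h (12 of 100 reached 241, highest other 2141) and 120 h (8 of 100 reached 4077, highest other 9416), or for V710370 against SLOAN at 72 h (5 of 100 reached 3605, highest other 8863). For V710370 against SLOAN at 120 h 2 of 100 reached 7116, under the bound of 5% set beforehand. The highest other split gave more calls, 8728, and for the reason given next these splits do not settle the cultivar pairs. Splits of the lists that are uneven in treatment keep part of the infection effect, and those of the cultivar pairs take in the cultivars' level differences by construction. In balanced splits the lists were called most often in the real one, 1 of 100, with highest others of 3 at 72 h and 6 at 120 h. The other balanced splits hold no treatment difference, so camera at the preset correlation can call lists without one. Single lists close to the threshold may be such calls. With cultivar levels removed the real counts were the highest, 1 of 100 for each pair and time, with highest others of 32 and 2517 for CONRAD and 543 and 1618 for V710370 at 72 h and 120 h.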

How the results depend on the processing

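The alternatives were planned before the data were examined except the restriction to cultivars by added *P. sojae* RNA, the symbol background, the block on centred values, and leaving out OX20-8 arrays or 1 of them, which were chosen after the data were seen. Apart from the values below, results kept their direction and their side of the threshold: 291 counts stayed within 1.5 times and 28 did not, 3532 values of named genes kept their call, 16 lost it, 4 gained it and 6 reversed, 557 list results kept theirs, 43 lost it and 16 gained it, and 63 signal results kept theirs, 6 lost it and 12 gained it; with each replicate letter left out, 111 counts stayed and 21 moved, 1315 gene values kept their call, 4 lost it and 1 gained it, 219 list results kept theirs, 4 lost it and 1 gained it, and 44 signal results kept theirs. The losses were EXP4 at 120 h without replicate V (-0.36), W (-0.21) or Y (-0.27), RPS13 at 72 h without Z (0.05), and the lists of jasmonate genes at 72 h without V (adjusted p = 0.0551), forisome genes at 120 h without Y (adjusted p = 0.0565) and NAC genes at 120 h without W or Y (adjusted p = 0.0710 and 0.0602). With soybean probe sets centred, CONRAD against SLOAN at 120 h gave 2360 and V710370 against SLOAN 3716, and quantile-normalized 1766 and 2919, since the shift between arrays is taken out by construction. With no filter the *P. sojae* counts were 9641 at 72 h, 10155 at 120 h and 6852 among cultivars, and with the 99th percentile 2497, 2478, 2213 and, over time, 1598, since more or fewer probe sets were tested. With replicate letters as a block, CONRAD against SLOAN gave 809 at 72 h and 6198 at 120 h, and V710370 against SLOAN 6075 at 72 h; the block also ended the calls of the NAC list at 120 h (adjusted p = 0.0543) and of the correlations given below, added that of EXP2 at 120 h (adjusted p = 0.041) and changed no other call. With letters and title numbers as blocks the counts at 72 h were 528 and 1923. With the *P. sojae* signal as a covariate they were 2958 and 7194, mostly higher in place of mostly lower, and *P. sojae* over time 677 and among cultivars 620; the cause was not tested. In the 4 cultivars with the least added *P. sojae* RNA, the effect of time on infection gave 2319 and mock time 5214, with fewer arrays. Of the gene lists, 9 at 72 h and 11 at 120 h passed; with an estimated correlation 0 and 0 did, with all probe sets of a gene 17 and 17, and against genes with a symbol 3 and 7. Camera was not run with a variance trend. For the correlations with the *P. sojae* signal, using the share, Pearson's r was 0.369 at 72 h and 0.338 at 120 h for pathogenesis-related genes, 0.269 with cultivar means subtracted at 120 h, and -0.400 for photosynthesis at 120 h, all no longer past the threshold, while Spearman's rho passed for each (0.530, 0.654, 0.566 and -0.652). With letter means subtracted r for pathogenesis-related genes at 120 h was 0.421, and 0.276 with cultivar means subtracted, also no longer past it (rho 0.578, past it, and 0.345, not past it); rho for photosynthesis at 72 h with cultivar means subtracted also left it, at -0.373. Without the 2 arrays farthest from the median signal, these passed: isoflavonoid 0.608 at 72 h and 0.577 at 120 h, and with cultivar means subtracted isoflavonoid 0.458 and 0.431, and at 72 h pathogenesis-related 0.405 and photosynthesis -0.396. Without the OX20-8 arrays the same ones passed, with 0.638, 0.611, 0.465, 0.425, 0.404 and -0.399; the cause was not tested. Genes that reversed were LOX7 at 72 h (-0.00705) and CYSTATIN at 120 h (-0.14) in the least-spiked cultivars, and CYP34 at 120 h, centred (-0.0834), quantile-normalized (-0.11), with the covariate (-0.14) and with the block on centred values (-0.0834), of which LOX7, CYSTATIN and CYP34 had 0.62, 0.04 and 0.00 before; the cause was not tested. With a replicate letter left out, which leaves fewer arrays, the counts ranged from 6658 to 11142 for ATHOW and 5997 to 10189 for V710370 at 72 h, 6108 to 9749 for ATHOW at 120 h, 57 to 155 and 1593 to 2727 for CONRAD against SLOAN at the 2 times, 1029 to 2811 and 3756 to 5715 for V710370 against SLOAN, 4633 to 8261 and 11037 to 15851 for cultivar and infection, and 1410 to 2239 for *P. sojae* over time; for infection they ranged from 21338 to 22113 and 21958 to 22534. Without only the inoculated OX20-8 array of replicate W at 120 h, the array with the highest *P. sojae* share of its treatment, every count stayed within 1.5 times: ATHOW 11621 at 72 h and 9947 at 120 h, V710370 10593 at 72 h, the CONRAD pair 258 and 4361, the V710370 pair 3823 and 7401, and cultivar and infection 10219 at 72 h. Signal over background limits the *P. sojae* results: 33.4% of its probe sets passed the filter against 72.6% for soybean.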

Other observations

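Gene groups written from the annotation's symbols, before any group difference was computed, add to the lists above. All 9 calmodulin and calcium-dependent kinase genes rose at both times (medians 0.45 and 0.60, camera adjusted p = 0.00392 and 0.00389; adjusted p = 0.114 and 0.109 with an estimated correlation), with SCAM-5, below background in all mock arrays, at 1.18 and 1.78 or more, CDPK at 1.31 and 1.25 (SE 0.04) and SCAM-1 at 0.36 and 0.55 (SE 0.03). Fatty acid desaturase genes rose in 8 of 9 cases at 72 h and 9 of 9 at 120 h (medians 1.44 and 1.02, adjusted p = 0.000285 and 0.00256; adjusted p = 0.0689 and 0.125 with an estimated correlation), among them FAD2-2 by 1.46 and 1.99 (SE 0.05), FAD2-3 by 1.52 and 1.86 (SE 0.05) and SACPD-C by 1.92 and 2.97 (SE 0.11). Isoflavone conjugation and other flavonoid genes rose in 6 of 7 cases at each time (medians 0.78 and 1.12, adjusted p = 0.00542 and 0.00594; adjusted p = 0.0689 and 0.0966 with an estimated correlation), F6H1 by 2.11 and 4.49 (SE 0.12), UGT708D1 by 1.29 and 1.52 (SE 0.06) and IF7MaT by 1.35 and 1.95 (SE 0.08). Cysteine synthesis genes rose in 7 of 7 and 6 of 7 cases (medians 0.51 and 0.57, adjusted p = 0.00930 and 0.0137; adjusted p = 0.179 and 0.201 with an estimated correlation), OAS-TL3 by 2.65 and 1.86 (SE 0.06), OAS-TL2 by 1.17 and 1.49 (SE 0.10) and OAS-TL1 by 0.52 and 0.86 (SE 0.03). Forisome and sieve element genes fell in 6 of 7 cases and rose in 1 (medians -0.94 and -1.15, adjusted p = 0.0804 and 0.0342; adjusted p = 0.441 and 0.458 with an estimated correlation), with SEOA at -1.14 and -1.64 (SE 0.08), SEOF at -0.97 and -1.37 (SE 0.07) and SEO-F3 at -0.94 and -1.15 (SE 0.06). MYB genes fell in 29 of 48 cases at each time and rose in 9 and 12 (medians -0.33 and -0.49, adjusted p = 0.0816 and 0.0335; adjusted p = 0.479 and 0.458 with an estimated correlation), while MYB184 rose by at least 4.10 at 72 h, where no mock array was above background, and by 5.36 at 120 h, where 1 of 32 was (SE 0.09), MYB73 by 2.29 and 3.36 (SE 0.08), MYB92 by 2.19 and 3.11 (SE 0.08) and MYB29 by 1.91 and 2.40, and MYB112 stood at -1.80 and -1.91. NAC genes rose in 10 of 15 cases and fell in 4 and 3 (medians 0.74 and 0.88, adjusted p = 0.0568 and 0.0491; adjusted p = 0.441 and 0.458 with an estimated correlation, and 0.0543 at 120 h with the letters as a block), NAC4 by 1.90 and 1.81, NAC3 by 1.73 and 2.01 and NAC27 by 1.90 and 1.75 (SE 0.07 to 0.08). Against a background of genes with a symbol of their own, a setting chosen after the data were seen, camera no longer called the cysteine synthesis genes (adjusted p = 0.0927 and 0.0969), the isoflavone conjugation genes (adjusted p = 0.0733 and 0.0565), the calmodulin genes at 72 h (adjusted p = 0.0646) or the NAC genes at 120 h (adjusted p = 0.287). It called the desaturase genes (adjusted p = 0.0161 and 0.0440) and, at 120 h, the calmodulin (adjusted p = 0.0478), forisome (adjusted p = 0.0478) and MYB genes (adjusted p = 0.0169).

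The remaining groups did not pass camera at either time. GASA peptide genes fell in 8 of 12 cases and rose in 3 and 2 (medians -0.55 and -0.45, adjusted p = 0.151 and 0.126), with GASA14 at -2.85 and -2.18, GASA27 at -2.29 and -3.05 and GASA24 at -0.83 and -1.33. Glyoxalase genes rose in 6 of 9 cases and fell in 2 (medians 0.26 and 0.37, adjusted p = 0.231 and 0.224), with GLYI-19 at 3.92 and at least 4.68, GLYI-6 at 0.74 or more and 1.94 and GLYII-6 at -1.39 and -1.11. Cytochrome P450 genes rose in 9 of 21 cases and fell in 7 at 72 h, and 10 and 9 at 120 h (medians 0.06 and 0.05, adjusted p = 0.712 and 0.496), with CYP82A2 at 3.43 and 4.94 and CYP82A3 at 2.78 and 3.92. Phosphate supply genes rose in 6 of 15 cases and fell in 9 at 72 h, and 7 and 6 at 120 h (medians -0.25 and 0.09, adjusted p = 0.845 and 0.955), and camera pointed down at 120 h; PT01, also named G2DT-2, a prenyltransferase of glyceollin synthesis, stood at 3.33 and 4.61, PHR13 at -1.02 and -1.03 and PAP02 at 0.49 and 0.85. Of 50 bZIP genes 16 rose and 22 fell at 72 h, and 19 and 17 at 120 h (medians -0.01 and 0.02, adjusted p = 0.927 and 0.914), with BZIP111 at 2.09 and 2.39, BZIP10 at 1.09 and 1.63 and BZIP117 at -1.07 and -1.36, and camera pointed down at 120 h. The medians at 120 h of the bZIP, P450 and phosphate groups went to -0.07, -0.04 and 0.00 with centring. Heat shock transcription factor genes rose in 5 of 8 cases at 72 h and 6 at 120 h and fell in 3 and 1 (medians 0.26 and 0.40, adjusted p = 0.358 and 0.188), with HSF-15 at 0.55 and 0.64, HSF-01 at 0.25 and 0.47 and HSF-35 at 0.98 and 0.65. Seed maturation genes fell in 6 of 10 cases and rose in 3 and 4 (medians -0.40 and -0.33, adjusted p = 0.103 and 0.233), with PM35 at 0.62 and 2.76, LEA-2 at -1.30 and -1.22 and PM40 at -1.76 and -2.08.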
